A study of Escherichia coli with 4 samples.

How the data were processed

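The data were the processed values of 4 Affymetrix E. coli Antisense Genome arrays, 2 of strain W3110 and 2 of a luxS mutant of it. Per the labels' protocols, cells were grown in LB at 30 °C, shaken at 250 rpm (flasks of 50 ml), to an optical density of 2.4, total RNA was extracted with a Qiagen RNeasy kit, and fragmented cDNA was end-labelled with biotin. The deposited values were intensities: 1 MAS5 signal per probe set and array on a linear scale, which the authors made with MAS5 version 5.1 per the submitters' processing notes. The scaling target, detection calls and any filter were not given in the sources used here. The trimmed mean of all probe sets, leaving out 2% at each end, was 500.2 on each array, so each had been scaled by a single factor to the same level. The median signal of gene probe sets was 257 and 231 on the wild type arrays (replicates 2 and 3) and 267 and 270 on the mutant arrays (replicates 1 and 2), and that of intergenic probe sets was 74.1, 70.0, 79.6 and 72.4. Arrays give no counts, so the number of arrays and the signal over background limit the precision.

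The table held 7312 probe sets: 4345 named for a gene by its b-number, 2886 intergenic, 22 manufacturer's controls and 59 for phages, plasmids and a cloning vector. Each b-number was matched to the locus tags of the MG1655 assembly ASM584v2, a related K-12 strain, which was used for current symbols and for gene neighbours only. Of the gene probe sets, 4183 matched and 162 kept the array's name. For 4142 of the 4151 that could be compared, the gene ID was the same as in the platform's own annotation. That annotation gave 1 symbol for 3656 gene probe sets, several for 589 and none for 100, and no name was taken from it. The probe sets of 126 genes carry a suffix for probes shared between genes, and their values may hold signal of near-identical copies.

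Groups and replicate numbers were taken from the sample titles. Signals were tested as log2(signal + 12.1), where 12.1 is the 5th percentile of gene probe set values over all arrays, and fold changes are on this scale except in the count over pairs of arrays, which used the deposited signals. The scale understates changes of low-signal genes. Genes with a mean signal over all arrays under 97.1, the 25th percentile, were left out, and 3259 were tested. The 2 groups were compared with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The groups share only 1 replicate number, so no block was fitted. Standard errors are the moderated ones of this fit. Its prior and trend borrow spread across genes, and the test could therefore call genes with 2 arrays a group.

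Before the data were examined, 25 gene lists were fixed by b-number. They covered AI-2 uptake and processing, genes next to luxS, methionine and the methyl cycle, sulfur assimilation and cysteine, flagellum, chemotaxis, biofilm factors, colanic acid, RpoS general stress, acid resistance, heat shock, cold shock and the SOS response. They also covered ribosomal proteins, sugar and glycerol catabolism, amino acid catabolism, the TCA cycle and glyoxylate, anaerobic respiration and fermentation, iron acquisition, amino acid biosynthesis, purine and pyrimidine biosynthesis and the e14, Rac, DLP12 and CP4-57 prophages. Lists with at least 3 tested members were compared with all other genes by camera (preset correlation 0.01), again with an estimated correlation, and by fry, which tests whether a list's own genes move one way on balance, with adjustment over the lists. A list of nitrogen-limitation genes was added after the values were seen. Genes named in the text were chosen by a rule fixed beforehand. It took luxS, then up to 12 genes per direction with the largest differences among those past the threshold whose groups did not overlap, filled up with genes of unadjusted p under 0.05, and up to 4 members of each list with the smallest p. Genes outside it (lsrC, tqsA, the genes around the lsr region, emrA, metH, metJ, metK, metR, amtB and the nitrogen genes of the closing section) were named after their values were seen.

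The fit was tested on 20 simulated data sets of the 3259 genes, with 200 genes changed at 2-fold or 4-fold. Spreads were drawn from the prior of this fit. It recovered 75.4% of the 2-fold and 98.4% of the 4-fold changes, 5.59% of its calls were false, and with no gene changed it made 0.05 calls on average. With the preset correlation, a shift of 0.5 in the flagellar list was found in 20 of 20 runs. Its recovery with an estimated correlation was not recorded. With no change, 1 list was called over all runs, or 0 with an estimated correlation. The simulated noise was normal and followed the model that was then fitted. The share of false calls therefore does not show that this rate holds in the data. The simulations drew genes independently, so they do not test lists whose members vary together. They also held no offset between arrays, and 200 changed genes loosen the adjusted threshold compared with the 8 called in the data. Recovery in the data may thus be lower: lsrC, at -0.97 (SE 0.147), did not pass.

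Alternatives were no pseudocount, 4 times the pseudocount, no filter, a filter at the median signal (257), quantile normalization, centring of each array on its median, no trend, a robust fit, all probe sets but controls, other thresholds and leaving out each array in turn. A cyclic loess adjustment between pairs of arrays and a count over pairs with the pseudocount were added after the data were examined. Intergenic probe sets were fitted apart, and their neighbours were found by matching the lengths of nearby gaps to the gene table. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 joined the tables and drew the plots. No coordinates are printed, since the array's genome build was not given in the sources used here.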

Results

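Transcript levels were measured in Escherichia coli K-12 strain W3110 and in a luxS mutant of it. LuxS makes the precursor of autoinducer 2 (AI-2), a small molecule that cells release and take up again as they grow, and in the same step returns homocysteine to the methionine pathway. Cells of both strains were grown in LB, a rich complex medium, with shaking at 30 °C and collected at an optical density of 2.4. The data comprised 4 Affymetrix antisense genome arrays, 2 of the wild type (replicates 2 and 3) and 2 of the luxS mutant (replicates 1 and 2), each with 4345 probe sets named for 1 gene. The labels do not say whether the arrays of a group came from separate cultures, so the p-values below measure only the spread between these arrays, which may be technical. The number of arrays sets the precision: an exact two-sided permutation test of 2 arrays against 2 cannot go below p = 0.333, and the comparisons therefore rest on a model fitted over all genes.

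The first value to be read was that of luxS (b2687) itself. Its signal was 723 and 570 on the wild type arrays and 70.0 and 90.5 on the mutant arrays, means of 647 ± 108 (SD, n = 2) and 80.3 ± 14.5 (SD, n = 2). The log2 difference of mutant minus wild type was -2.83 (SE 0.216), with an adjusted p of 0.00128 by limma. Its mutant signals were under the 95th percentile of phage, plasmid and vector probe sets (201 and 158), so the size of this difference is uncertain. Where the mutation lies relative to these probes is not given in the sources used here, and a probe outside the mutated part would not have checked the labels. The 6 tested genes next to luxS on the chromosome, among them gshA (glutathione synthesis) and the multidrug efflux genes emrA and emrB, did not pass the test as a list.

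The comparison asked which other transcripts depend on luxS in cells at this density. The clearest answer came from the lsr region, whose products import AI-2 (LsrA, LsrC, LsrD and LsrB), phosphorylate it (LsrK), process the phosphorylated form (LsrF and LsrG) and repress the region in its absence (LsrR). Transcripts of lsrG fell by 3.57 on the log2 scale (SE 0.132, 11.9-fold), from signals of 2305 and 2113 to 185 and 165. The first of these mutant signals was under the level given above for phage, plasmid and vector probe sets and the second over it, so the size of the fall is uncertain. Those of lsrB fell by 3.28 (SE 0.116, 9.73-fold), from 2773 and 2547 to 265 and 259. The transcripts of lsrF fell by 2.65 (SE 0.142), those of lsrK by 2.41 (SE 0.133) and those of tam, a methyltransferase gene next to lsrG, by 1.47 (SE 0.117). The smallest fall that passed was that of lsrR, which fell by 1.14 (SE 0.111) and kept signals of 799 and 792 on the mutant arrays. Adjusted p by limma was 1.52e-05 for lsrG and for lsrB, 1.48e-04 for lsrF and for lsrK, 0.00151 for tam and 0.00458 for lsrR. The call of lsrR was lost without the trend in the variance model (adjusted p = 0.0847).

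**Figure D1:**
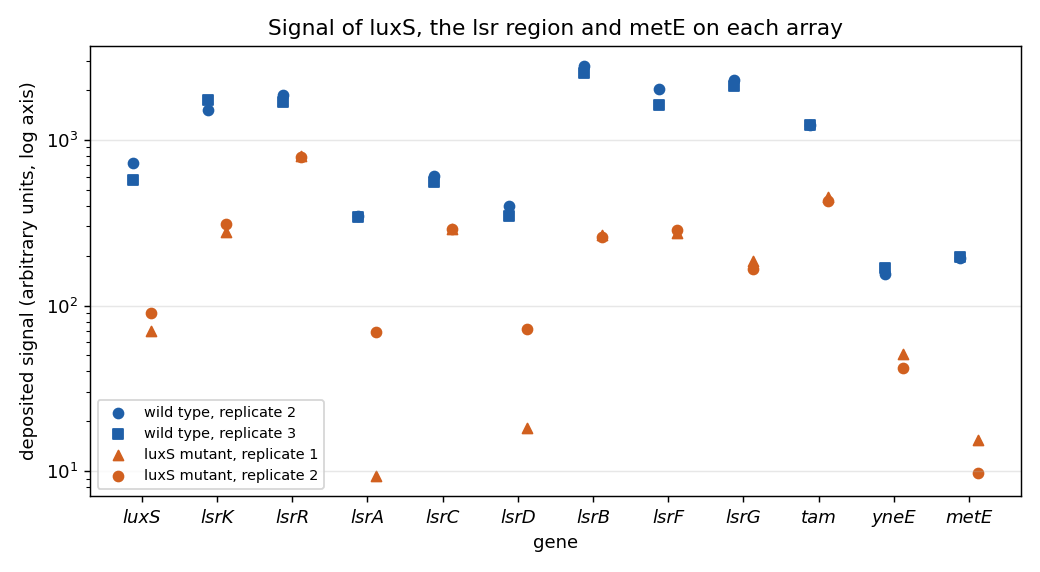
Deposited signal (arbitrary units, log axis) of luxS, the genes from lsrK to yneE and metE on each of the 4 arrays, with wild type replicates in blue and luxS mutant replicates in orange. For each gene shown, both mutant points lie under both wild type points, from 799 and 792 against 1858 and 1681 for lsrR down to 15.5 and 9.80 against 193 and 197 for metE.

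The remaining transporter genes of the region were lower on both mutant arrays but did not pass. The signal of lsrA was 349 and 343 in the wild type and 9.39 and 69.1 in the mutant, a log2 difference of -3.10 (SE 0.544) with an adjusted p of 0.134 by limma. For lsrD it was 400 and 346 against 18.1 and 72.4, a difference of -2.93 (SE 0.443, adjusted p 0.0683). For lsrC it was 603 and 554 against 289 and 288, a difference of -0.97 (SE 0.147, adjusted p 0.0683). The mutant arrays of lsrA and lsrD disagreed by more than those of their neighbours, at signals under the level given above for phage, plasmid and vector probe sets. Their calls depended on the setting: with 4 times the pseudocount, adjusted p by limma was 0.0352 for lsrA and 0.0209 for lsrD. Of the 10 genes listed for AI-2 uptake and processing, 9 were tested, the exception being the low-signal gene tqsA. Among these 9, 6 passed over all genes tested and 9 when adjusted over the list alone, and their median log2 difference was -2.65. Limma's camera test with its preset correlation gave the list an adjusted p of 9.1e-34, and the rotation test fry gave 0.0101. The call was lost without the preset, at an adjusted p = 0.25 with an estimated correlation. That was the lowest adjusted p of the 25 lists in this version of camera, although all 9 genes were lower. A call lost with an estimated correlation, here or for the lists below, therefore does not decide whether a list shifted.

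The lower signal had a sharp edge at the lsrK end of the region. On the lsrK side, the toxin and antitoxin genes hipA and hipB differed by 0.18 (SE 0.137) and -0.09 (SE 0.117), and b1509 and ydeK by 0.38 (SE 0.157) and 0.16 (SE 0.16), without passing. On the other side, yneE, which follows tam, had signals of 156 and 167 against 51.3 and 42.2, a log2 difference of -1.56 (SE 0.245) that did not pass (adjusted p 0.0768 by limma) and whose size is uncertain at such low signal. The next gene, uxaB, differed by 0.11 (SE 0.256), with an adjusted p of 0.885. Its wild type signals of 111 and 85.0 were under the 95th percentile of phage, plasmid and vector probe sets (144 and 108), so it could hardly have shown a fall. Further on, yneG differed by -0.46 (SE 0.251, adjusted p 0.585 by limma), and the edge on this side is therefore uncertain.

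**Figure D2:**
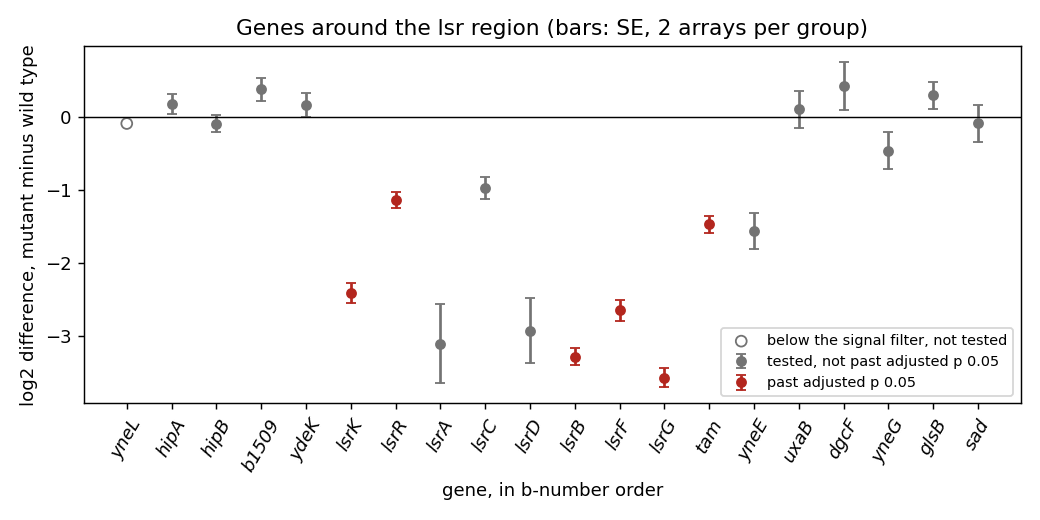
Log2 difference of mutant minus wild type for 20 neighbouring genes in b-number order, with bars of 1 SE from 2 arrays per group, and red points for those past an adjusted p of 0.05. Differences from -0.97 to -3.57 span lsrK to yneE, while hipA, hipB, b1509 and ydeK on one side and uxaB, dgcF, yneG, glsB and sad on the other lie between -0.46 and 0.42.

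Outside the lsr region, the gene that fell was metE, which encodes the cobalamin-independent methionine synthase that methylates homocysteine. Its signal was 193 and 197 in the wild type and 15.5 and 9.80 in the mutant, a log2 difference of -3.07 (SE 0.273) with an adjusted p of 0.00274 by limma. The mutant values lie near the floor set by the pseudocount of 12.1, so the difference understates the change in signal. Without wild type replicate 3 the adjusted p of metE was 0.144 at a difference of -3.06. Other genes of methionine synthesis and the methyl cycle did not pass. The signal of metB was 348 and 191 against 458 and 496, that of metA, the first enzyme of the pathway, 296 and 286 against 426 and 405, and that of mmuP, an S-methylmethionine transporter gene, 219 and 96.3 against 315 and 323. The cobalamin-dependent synthase gene metH differed by 0.10 (SE 0.22), the regulator gene metJ by 0.01 (SE 0.13) and metK, which makes S-adenosylmethionine, by 0.23 (SE 0.118). Over the 16 genes of this list, 1 passed (1 also when adjusted over the list alone), the median was 0.14 and the mean -0.01, so that they differed in sign, and camera gave an adjusted p of 0.797. Its median was 0.01 when arrays were centred on their medians, 0.03 after quantile normalization and 0.08 without wild type replicate 3. In sulfur assimilation and cysteine synthesis, 0 of 19 genes passed in limma (0 adjusted over the list alone). The taurine transporter gene tauC had signals of 167 and 164 against 258 and 312, and the regulator gene cysB 766 and 745 against 1128 and 939. This list had a median of 0.08 (adjusted p 0.797), which turned to -0.05 when arrays were centred on their medians, a step that lowers all genes alike, and was 0.04 after quantile normalization.

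Over the 3259 genes tested, limma called 8 lower in the mutant and 0 higher at an adjusted p under 0.05. The 8 were luxS, lsrB, lsrG, lsrF, lsrK, lsrR, tam and metE. At an adjusted p under 0.1 the counts were 11 lower and 1 higher, the higher gene being amtB, which encodes an ammonium transporter. At an unadjusted p under 0.05, 88 genes were lower and 197 higher, against 163 that chance would give in all. The balance between directions depended on the scaling, with 192 lower and 88 higher when arrays were centred on their medians and 150 and 123 after quantile normalization. With a 2-fold difference added, 12 were lower and 21 higher. The counts moved when single arrays were left out: 54 lower and 54 higher without wild type replicate 2, 7 and 1 without wild type replicate 3, 17 and 8 without luxS mutant replicate 1, and 23 and 24 without luxS mutant replicate 2. In each of these 4 fits the lone array of its group is assumed to vary like the others, and 7 or 8 of the 8 genes named above were called. The arrays of the groups did not overlap for 43.7% of the genes tested, against 33.3% by chance, with 948 higher and 477 lower in the mutant. This was counted on the deposited signals alone, so the share and its balance may also depend on the scaling.

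On the deposited signals, a difference of at least 2-fold in all 4 pairings of a mutant with a wild type array was found for 11 lower and 3 higher genes. The 11 were the 8 above with lsrA, lsrD and yneE. The 3 were fixB (85.5 and 57.9 against 182 and 192), an electron transfer flavoprotein gene, ybhP (70.2 and 67.1 against 187 and 158) and insF4 (43.2 and 18.3 against 258 and 98.2). The insertion sequence gene insF4 shares its probes with near-identical copies, so its signal cannot be given to 1 copy. With the pseudocount added, 11 lower genes and 1 higher gene, ybhP, kept such a difference. None of the 3 passed, with adjusted p by limma of 0.254, 0.235 and 0.366. Genes of pyrimidine degradation were among the largest positive differences that did not pass, with rutA at 1.37 (SE 0.349) and rutC at 1.08 (SE 0.402). Others were yphD at 1.40 (SE 0.432), yphG at 1.13 (SE 0.473), the serine deaminase gene sdaB at 1.16 (SE 0.325), the prophage gene ynaK at 1.24 (SE 0.312), ycjO at 1.26 (SE 0.455), hybD at 1.13 (SE 0.411) and scpB at 1.11 (SE 0.262). The glycine tRNA gene glyY, whose probes are also shared, had a difference of -1.08 (SE 0.407), with signals of 983 and 340 on the mutant arrays. Low signal limits these positive differences. On both wild type arrays fixB, ybhP, insF4, rutA, yphD, sdaB, ynaK, ycjO and scpB, and on replicate 3 alone rutC and yphG, lay under the 95th percentile of phage, plasmid and vector probe sets (144 and 108). Those probe sets were themselves higher in the mutant by a median of 0.48. The genes at least 2-fold higher at an unadjusted p under 0.05 had a median signal of 130, against 412 for all tested genes. The values also depended on single arrays. With arrays left out in turn, the difference ranged from 0.322 to 1.95 for yphG, 0.382 to 1.88 for hybD, 0.399 to 1.76 for rutC, 0.699 to 2.09 for yphD, 0.497 to 2.03 for ycjO and 0.765 to 1.55 for sdaB. It ranged from 0.901 to 1.83 for rutA, 0.85 to 1.63 for ynaK, 1.43 to 2.72 for insF4 and -1.83 to -0.331 for glyY.

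**Figure D3:**
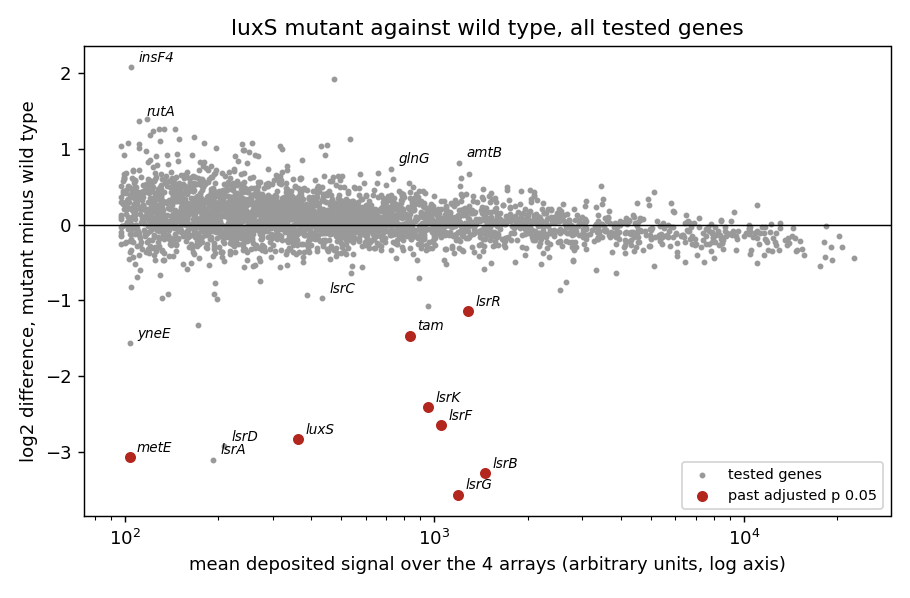
Log2 difference of mutant minus wild type against mean deposited signal (arbitrary units, log axis) for the 3259 genes tested, with the 8 genes past an adjusted p of 0.05 in red. The red points lie from -1.14 (lsrR) to -3.57 (lsrG), below the main body of genes, and the median of all tested genes is 0.07.

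Among the other gene lists fixed before the data were examined, those of the ribosomal proteins and of cold shock were lower in the mutant by small amounts. Of the 54 ribosomal protein genes 44 had a negative difference, with a median of -0.12, and 0 passed in limma or when adjusted over the list alone. The signal of rplY was 5028 and 7178 against 3908 and 4353, and that of rpsI 2230 and 2868 against 1983 and 1909. Camera called the list at an adjusted p of 7.22e-06, but fry gave 0.452, and the call was lost at an adjusted p = 0.823 with an estimated correlation. After quantile normalization the median was -0.03 (adjusted p 0.855), and without wild type replicate 3 it was -0.04 (adjusted p 0.0181). That array also had the highest signal over the 18 ribosomal RNA probe sets, a median of 20380, against 12830 on the other wild type array and 13980 and 11930 on the mutant arrays. All 8 cold shock genes had a negative difference, with a median of -0.26 and an adjusted p of 2.18e-04 by camera. This call too was lost, at an adjusted p = 0.611 with an estimated correlation, and fry gave 0.103. The RNA chaperone gene cspA had signals of 1864 and 1708 against 1349 and 1157 (adjusted p 0.386), the only member that passed when adjusted over the list alone, while 0 passed over all genes in limma. The others included pnp at -0.30 (SE 0.12) and cspE at -0.30 (SE 0.13).

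Groups linked to AI-2 signalling, motility and surface growth did not pass. The 39 flagellar genes had a median of 0.03 (adjusted p 0.622 by camera), with fliI at 0.43 (SE 0.156) and fliT at -0.40 (SE 0.153), and the 11 chemotaxis genes one of -0.04 (adjusted p 0.359), with cheZ at -0.25 (SE 0.132) and the serine receptor gene tsr at 0.24 (SE 0.108). Of the 29 listed genes of curli, fimbriae, cellulose and other biofilm factors, 16 were tested, with a median of 0.18 (adjusted p 0.622). The signal filter left out most curli genes and the listed cellulose synthase genes, so this result does not cover them. In that group pgaC, of biofilm polysaccharide synthesis, had signals of 118 and 78.1 against 178 and 177, and flu, the antigen 43 adhesin gene, 1280 and 1431 against 1718 and 1712. The 6 colanic acid genes tested had a median of 0.31 (adjusted p 0.106). In these 4 lists 0 members passed in limma, over all genes or adjusted over the list alone. Centring arrays on their medians turned the flagellar median to -0.10 by the same shift of all genes, and it was 0.04 after quantile normalization. Quantile normalization turned that of chemotaxis to 0.01. Without wild type replicate 3 the flagellar median was 0.00562 and that of chemotaxis 0.000612. The biofilm median was 0.05 after such centring, 0.03 after quantile normalization and -0.01 without wild type replicate 3, and the colanic acid median 0.18, 0.13 and 0.17.

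Several further lists lay close to the threshold by camera, while fry gave them adjusted p of 0.393, 0.313, 0.192 and 0.232, in the order below. The genes next to luxS had a median of 0.49 (adjusted p 0.0659 by camera), with all 6 positive, emrB at 77.5 and 81.0 against 179 and 107, and gshA at 1619 and 1028 against 1604 and 1847. Without wild type replicate 3 their median was 0.06 (adjusted p 0.748), and without wild type replicate 2 it was 0.72 (adjusted p 0.00611). The 26 iron acquisition genes had a median of 0.28 (adjusted p 0.0659), with sufA, of iron-sulfur cluster assembly, at 238 and 226 against 325 and 334. Their median was 0.15 when arrays were centred on their medians, 0.13 after quantile normalization and 0.17 without wild type replicate 3. The 22 genes of amino acid catabolism had a median of -0.05 (adjusted p 0.0659), and 2 of them passed when adjusted over the list alone: the proline dehydrogenase gene putA, at 1088 and 1126 against 744 and 610, and the proline transporter gene putP, at 1641 and 1822 against 1070 and 1230. Their adjusted p over all genes was 0.195 and 0.269 in limma. The median of this list was -0.18 when arrays were centred on their medians, -0.01 after quantile normalization and -0.02 without wild type replicate 3. The 4 Rac prophage genes tested had a median of 0.55 (adjusted p 0.086), and 1 of them, ynaK, passed when adjusted over the list alone. Their median was 0.36 after quantile normalization and 0.35 without wild type replicate 3. Low signal limits this list. On both wild type arrays pinR, whose probes are shared between genes, and ynaK lay under the 95th percentile of phage, plasmid and vector probe sets (144 and 108). Those probe sets were themselves higher in the mutant by a median of 0.48.

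The stress and metabolic lists that remain had no member past the threshold in limma, over all genes or adjusted over the list alone. Camera's adjusted p was 0.674 for 23 genes of RpoS general stress (median 0.08), 0.793 for 16 heat shock genes (0.09) and 0.971 for 16 genes of the SOS response to DNA damage (0.08). It was 0.797 for the 3 of 14 listed acid resistance genes that were tested (0.12). It was 0.331 for 51 genes of sugar and glycerol catabolism under the regulator CRP (median -0.02), 0.674 for 18 genes of the TCA cycle and glyoxylate (-0.03) and 0.622 for 19 genes of anaerobic respiration and fermentation (0.13). It was 0.797 for 30 genes of aromatic, histidine, arginine and branched-chain amino acid synthesis (median 0.10) and 0.971 for 22 genes of purine and pyrimidine synthesis (0.04). Among the prophages it was 0.797 for 8 genes of e14 (median 0.31), 4 of DLP12 (-0.02) and 9 of CP4-57 (-0.0039). Of these 12 medians, 5 changed sign after quantile normalization: those of acid resistance, sugar and glycerol catabolism, the TCA cycle, amino acid synthesis and purine and pyrimidine synthesis. The e14 median fell to 0.15 after quantile normalization and 0.04 without wild type replicate 3. In the same 2 fits the DLP12 median was -0.118 and -0.145, that of CP4-57 -0.152 and -0.119 and that of anaerobic respiration and fermentation 0.0263 and 0.0591. Without that array the acid resistance median was 0.27, that of the SOS response turned to -0.00794 and that of the TCA cycle to 0.0374. Single members included the ribose transporter gene rbsA, at 1065 and 1032 against 1381 and 1397, the succinate dehydrogenase gene sdhC, at 3394 and 2348 against 3882 and 4195, and the chaperone gene grpE, at 436 and 314 against 576 and 538, none of which passed.

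**Figure D4:**
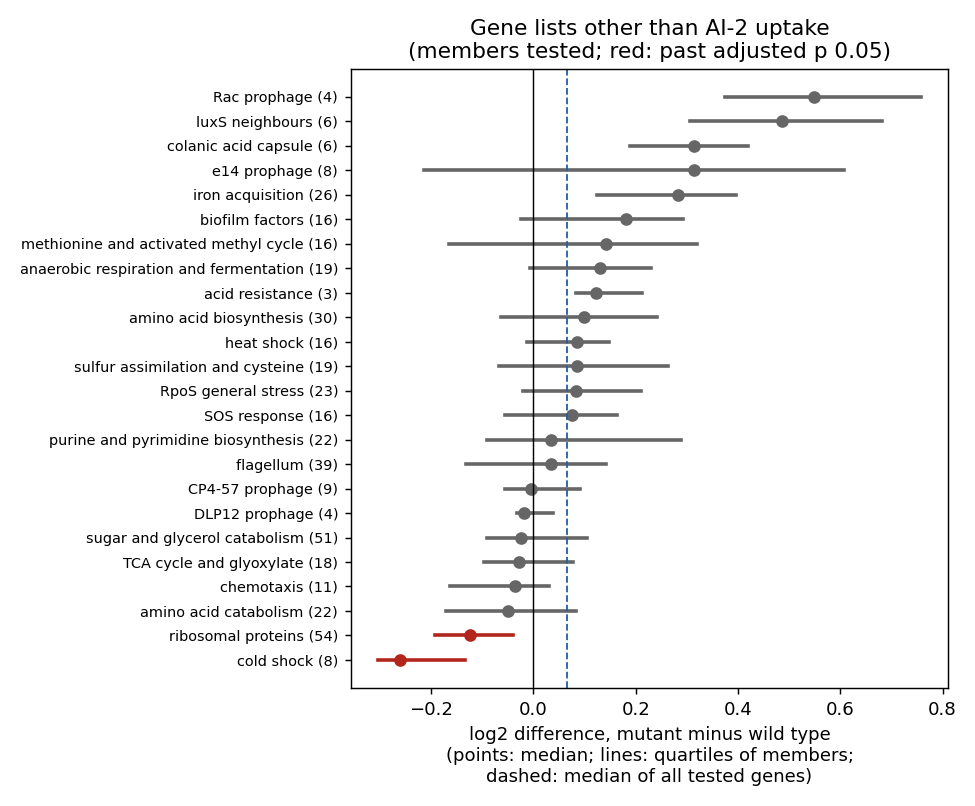
Median (points) and quartiles (lines) of the log2 difference of mutant minus wild type over the tested members of each gene list other than AI-2 uptake, with the number of members in brackets, a dashed line at the median of all tested genes (0.07) and red for lists past an adjusted p of 0.05 by camera. The ribosomal protein and cold shock lists lie lowest, at -0.12 and -0.26, and the genes next to luxS and those of the Rac prophage lie highest, at 0.49 and 0.55, without passing.

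Arrays agreed closely across genes, and those of a group not always more than those of different groups. Pearson's r of the log2 values was 0.980 between the wild type arrays and 0.983 between the mutant arrays, and 0.981 between wild type replicate 2 and luxS mutant replicate 2, across genes, which are not independent replicates. The log2 difference had an SD of 0.357 between the wild type arrays and 0.292 between the mutant arrays. Between groups it was 0.358 and 0.317 with wild type replicate 2, and 0.463 and 0.418 with wild type replicate 3. The median log2 difference of mutant minus wild type was 0.18 in the quartile of tested genes with the lowest signal and -0.04 in that with the highest.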

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

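The fit of the intergenic probe sets was planned before the data were examined, while the tests of a mislabelled array, of gene loss, of an offset of 1 array and of matched lists were chosen after the results were seen. Probe sets between genes were outside the main measurement. Among the 1238 of them that were tested, limma called 2 lower in the mutant and 0 higher, with 51 lower and 58 higher at an unadjusted p under 0.05. Both lay in the lsr region. The probe set between lsrK and lsrR had signals of 3463 and 3466 in the wild type and 1135 and 1240 in the mutant, a log2 difference of -1.54 (SE 0.127, adjusted p 0.00637). The probe set between lsrG and tam had signals of 460 and 346 against 80.0 and 37.9, a difference of -2.60 (SE 0.31, adjusted p 0.0381) whose size is uncertain, since the mutant signals were under the 95th percentile of phage, plasmid and vector probe sets (201 and 158). Their neighbours were found from gap lengths, which matched the gene table for 22 of 30 and 26 of 34 nearby gaps.

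The lower signal of the lsr genes, tam and metE in the luxS mutant was weighed against a mislabelled array and a loss of the genes themselves. A mislabelled array is argued against by luxS, whose lower wild type signal was 6.3 times its higher mutant signal. Loss of the whole lsr region is argued against by 6 of 9 genes (lsrB, lsrC, lsrF, lsrK, lsrR and tam), whose signals on both mutant arrays were above the 95th percentile of the phage, plasmid and vector probe sets (201 and 158). A separate loss of lsrA, lsrD, lsrG or metE stays open, since 0 of these 4 genes were above that level on both mutant arrays and a silent gene would look the same. Less AI-2, and with it more repression by LsrR, is a candidate explanation for the lsr genes that the design names, as is less homocysteine for metE, but no sample with AI-2 or homocysteine added was analysed here and neither was tested.

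The lower signal of the ribosomal protein genes in the luxS mutant was weighed against an offset of 1 array and against a trend with signal. Random lists of genes matched on mean signal had a median log2 difference of -0.0938, with 95% of them between -0.136 and -0.0402, and the list's own median of -0.124 lay inside that range at percentile 6.66. The list may thus be lower only as other genes of high signal are. An offset of wild type replicate 3 cannot be told apart from a change in these genes. After quantile normalization the median went from -0.124 (quartiles -0.193 and -0.0392) to -0.0311 (quartiles -0.0787 and 0.0624) and the call ended because the shift itself shrank (adjusted p 0.855), while without that array it stayed past the threshold at a smaller median of -0.0411 (adjusted p 0.0181).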

How the results depend on the processing

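All alternatives here were fixed before the data were examined, except that the loess tests, the NtrC list tests and the pair count with the pseudocount were chosen after the results were seen. No result changed direction together with a call. No paired analysis was possible because the groups share only 1 replicate number. The number of genes lower stayed between 7 and 12 over 9 planned changes of pseudocount, filter, normalization, variance model or probe sets, with 0 higher in each and 2 of the 10 lower with all probe sets being intergenic, and 7 or 8 of the 8 genes named were called in each of them. With arrays left out in turn the counts ranged from 7 to 54 lower and from 1 to 54 higher, with wild type replicate 3 and wild type replicate 2 left out at the ends of both ranges, and the lone array of a strain was assumed to vary like the others. Other thresholds gave 1 higher (adjusted p under 0.1), 197 higher and 88 lower (unadjusted p under 0.05), 21 higher (2-fold as well) and 3 higher (2-fold in all 4 pairs of deposited signals, or 1 with the pseudocount added). At an unadjusted p under 0.05 the balance turned to 88 higher and 192 lower with median centring, 123 and 150 after quantile normalization and 117 and 158 after loess. Calls of luxS, lsrB, lsrG, lsrF, lsrK and tam held in all 13 alternatives run. The call of lsrR was lost without the trend (adjusted p 0.0847, lowest 2.32e-06) and that of metE without wild type replicate 3 (0.144, lowest 1.16e-11), and metE fell under the filter at the median. Centring arrays on their medians moved the median difference of tested genes from 0.0665 to -0.065, a shift of over 0.1, and gave 12 lower, adding lsrA, lsrC, lsrD and yneE. Of the values of named genes under alternatives, 702 stayed on their side of the threshold, 37 moved past it and 2 moved back.

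The number of lists past the threshold was 3, with 5 at the filter at the median, 6 with median centring, 5 with all probe sets but controls, 0 with an estimated correlation and 3 to 5 with arrays left out. With an estimated correlation, adjusted p was 0.25 for AI-2 uptake, 0.611 for cold shock and 0.823 for the ribosomal proteins. Since even AI-2 uptake did not pass there, these losses do not decide whether a list shifted. With fry, adjusted p was 0.103 for cold shock, 0.452 for the ribosomal proteins and 0.0101 for acid resistance, whose 3 genes fry takes on their own. Quantile normalization gave 0.855 for the ribosomal proteins. Median centring gave 0.0253 for the Rac prophage, 0.0218 for iron acquisition and 0.0177 for the genes next to luxS. The filter at the median gave 0.0398 for those neighbours and for amino acid catabolism. Iron acquisition reached 0.023 with no filter, 0.0228 with no trend and 0.0365 with all probe sets but controls, and the neighbours 0.0422 with the last. With arrays left out, adjusted p ranged from 0.00611 to 0.748 for the neighbours, 0.0491 to 0.481 for the Rac prophage and 0.0473 to 0.917 for chemotaxis. Except where the shift itself shrank (ribosomal proteins), the cause was not tested. After loess 11 genes were called lower and 1 higher (amtB, adjusted p 0.0499, range over settings 0.000439 to 0.187), 2 lists passed, and the ribosomal proteins had an adjusted p of 0.6. Low signal limits luxS, lsrA, lsrD, yneE and metE, whose mutant values lie near those of intergenic probe sets (median 79.6 and 72.4) or below.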

Other observations

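The nitrogen list and its tests were chosen after the values were seen, and the splits of the arrays were planned. Among tested genes with a mean wild type signal of 500 or more, amtB and glnG, which cells use when nitrogen is short, had the highest differences in the mutant. This cut was not fixed beforehand, and genes of lower signal had larger differences, such as hybD at 1.13 with a wild type mean of 360. The ammonium transporter gene amtB had signals of 843 and 889 in the wild type and 1410 and 1673 in the mutant, a log2 difference of 0.82 (SE 0.124) with an adjusted p of 0.0683 by limma. The regulator gene glnG, which encodes NtrC, had 509 and 572 against 891 and 928, a difference of 0.74 (SE 0.126, adjusted p 0.118). For glnK, which lies next to amtB, the signals were 1143 and 797 against 1570 and 1366, a difference of 0.61 (SE 0.177, adjusted p 0.522). The glutamine synthetase gene glnA differed by 0.05 (SE 0.106) and glnL by 0.09 (SE 0.108), so the other genes of the glnALG operon did not move with glnG, and the transporter gene glnH differed by less than 0.01 in size. Of 36 nitrogen-limitation genes tested, 29 had a positive difference, with a median of 0.185, 0 passed over all genes in limma and 2 passed when adjusted over the list alone, amtB and glnG, which had prompted the list. Without amtB, glnG, rutA and rutC, 0 passed over the list alone in limma. When arrays were centred on their medians, 19 of the 36 were positive and the median was 0.0537.

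The higher signal of nitrogen-limitation genes in the luxS mutant is a hypothesis found and tested on the same data. Camera compares the list with all other tested genes, and with 1 list its p is the same adjusted or not. It was 0.00133, and 0.000385 after quantile normalization with a median of 0.151 (0.0541 with an estimated correlation). The shift of the whole list thus outlasted quantile normalization. That list holds amtB, glnG, rutA and rutC, which prompted it, and the rest was not tested after this step. A signal-dependent offset between the arrays therefore stays open for the other members. Shared noise of co-transcribed genes cannot be told apart from a shift, since p was 0.102 with an estimated correlation. Nor can a shift carried by the members that prompted the list, since without amtB, glnG, rutA and rutC camera p was 0.0454 and 0.268 with an estimated correlation. Without wild type replicate 3 the list's median was 0.0914, and over the normalizations and arrays left out the adjusted p of amtB ran from 0.000439 to 0.187.

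An intergenic probe set placed between bioP and metE had signals of 209 and 161 in the wild type and 50.2 and 26.3 in the mutant, a lower level that did not pass (adjusted p 0.0554 by limma) and whose size is uncertain, since the mutant signals were under the median of intergenic probe sets (79.6 and 72.4). Its neighbours are less certain, since 6 of 32 nearby gaps matched the gene table. The gene metR (b3828) directly precedes metE (b3829) in b-number order, so this stretch may cover metR rather than lie between adjacent genes. The probe set of metR itself went the other way, at 199 and 126 against 221 and 294. Its log2 difference was 0.65 (SE 0.266) and did not pass (adjusted p 0.558 by limma). Probe sets for phages, plasmids and a vector, for which the labels name no target, gave a median difference of 0.48 over 59, with 14 higher and 0 lower at an unadjusted p under 0.05 and 0 called by limma. Among the manufacturer's controls, read after these values were seen, the BioB probe set had 225 and 188 on the wild type arrays against 720 and 475 on the mutant arrays. The groups overlapped for the BioC probe set, at 161 and 95.3 against 221 and 127, and for bla of the vector, at 25.3 and 8.27 against 9.0 and 36.2, while tet of the same vector had 13.9 and 11.7 against 24.6 and 70.2. The median of all 22 controls was 6.36 and 5.32 against 10.4 and 6.97. The mutant medians were higher, but all 4 lay under the pseudocount of 12.1, and those of wild type replicate 2 and luxS mutant replicate 2 were close. The cause of these differences was not tested. The 815 genes of the lowest signal quartile likewise had a median of 0.185.

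The 4 arrays can be split into groups of 2 in 3 ways, too few for a share under 0.05. The real split called 8 genes in limma, with 285 genes at an unadjusted p under 0.05. Each of the others called 0, with 63 and 80 genes at an unadjusted p under 0.05, under the 163 that chance would give. Both groups of those splits hold an array of each strain, so a strain difference counts there as spread within groups. Genes that differ by strain cannot be called in them. Their counts are thus no measure of chance for the real split, and no conclusion is drawn from them.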
